A study of Mus musculus with 10 samples.

How the data were processed

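Total RNA from dorsal skin of C57BL/6 mice was sequenced in 10 libraries, 3 Dlx4-WT and 3 Dlx4-KO at P1 and 2 of each genotype at P60. Per the labels, cDNA was made with a NEBNext kit, libraries with a NuGen kit, and sequencing was done on a HiSeq instrument, in the same way for all samples. The authors aligned the reads to mm10 with TopHat2 2.1.0 and calculated expression in Partek, whose version is not given in the sources used here. The deposited gene table holds RPKM values by the authors, scaled by gene length and by the alignments of each library, for 24543 entries. The gene annotation behind it is not given in the sources used here. The deposited comparison table holds group means on the log2 scale, made by the authors as log2 of RPKM with 0.1 added, which was checked against the RPKM table. It also holds a linear ratio of KO over WT by the authors, with p-values and q-values of an analysis of variance. The model behind these p-values was not checked here, so they are not taken as a like test to those made here. The authors' sheet of libraries gave the number of alignments and the sequencing run of each library.

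Low RPKM values of genes were compared with whole multiples of 1 read. In each library 55.9% to 65.7% of these values lay within 0.05 of a whole number of reads, where chance gives 10% for a read size set beforehand. The size of 1 read was chosen in each library to give the highest share, so 10% understates what chance gives. Most low values thus count whole reads, and why the others do not was not tested. The spacing gave about 30900000 to 66300000 reads per library behind the RPKM values. Approximate read numbers for Dlx4 were derived from it with the 2282 bp of the 3 exons in the basic GENCODE annotation. The full annotation gives 3269 bp, with which the read numbers would be higher and the limit in RPKM lower. As the detection limit 3 reads were taken, which covers counting error only. Spreadsheet software had turned 26 symbols into dates and 3470 entries were 0 in all libraries. Positions came from GENCODE release M21, which may not be the annotation the authors used.

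Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5) of the RPKM as deposited. Genes with at least 1 RPKM in at least 2 of the 10 libraries were kept, which left 14026. A single model with a mean for each of the 4 groups was fitted to all libraries, because the P60 groups alone leave few degrees of freedom, and variances were moderated with a mean-variance trend. Contrasts were KO minus WT at P1, KO minus WT at P60, their average, their difference, and P60 minus P1 averaged over genotypes. P-values were adjusted with the Benjamini-Hochberg method within each contrast, and genes at an adjusted p under 0.05 were called. Exact permutation tests were two-sided. P-values of single genes and of the permutation tests measure the spread between samples. In limma this spread was pooled over all 4 groups and moderated, so p-values at P60 also rest on the spread between P1 samples. The labels number the samples without saying how they relate to litters.

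Gene lists of cell types, pathways and complexes of skin, 35 in all, were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the lists, where at least 3 members were measured. At this preset value camera treats the genes of a list as nearly independent, so its p-values do not measure how far a list varies between samples. Of the 567 symbols of the lists 563 were found in the table. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes. Camera was first run with a variance trend and then with its default, as had been planned, after the first values had been seen. Lists, contrasts, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the Dlx genes, and at P1 and P60 the 8 largest changes in each direction among called genes whose KO libraries all lay on one side of the WT libraries. For the average and the difference it took 5 in each direction, for age 10, and where fewer than 5 passed, genes of the smallest p filled up to 5. From each called list it took the 4 members of the smallest p, and predicted genes, RIKEN clones, microRNAs and small nucleolar RNAs were passed over. Some list members that it named are left out of the text for length. Others are not reported here because they are withheld, and they stay in the fits and in the list tests.

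The procedure was tested on simulated data of the same design with 200 changed genes per run. At P1 it recovered 85% of genes changed by 1 on the log2 scale and 98% of those changed by 2, with 7 unchanged genes called. At P60 it recovered 73% and 94%, with 12 unchanged genes called. A list raised by 1 was called in both comparisons, with 0 other lists called. The simulated noise was drawn independently for each gene, so the genes of a list did not move together. The simulation therefore cannot show how often genes or lists are called falsely where genes do move together.

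The alternatives were pseudocounts of 0.1 and 1, no filter or a mean of at least 5 RPKM, median-of-ratios size factors, quantile normalization, the libraries of the compared age alone, robust moderation, array weights, the replicate number as a block, an adjusted p under 0.1, and leaving out each library in turn. When a library is left out at P60 the lone sample of its group is assumed to vary like the other groups. Added after the data had been seen were the share of muscle transcripts as a covariate, scaling without the muscle genes, a pseudocount of 0.1 without moderation, and camera with a variance trend. The replicate number was not used in the model reported, since samples of the same number did not resemble each other throughout at P1 (correlations of their deviations from the group mean of -0.17, 0.24 and -0.26). At P60, where 2 samples per group leave a single value, the correlation was 0.24.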

Results

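RNA sequencing measured gene expression in dorsal skin of C57BL/6 mice that carried an intact Dlx4 gene (WT) or an ablated one (KO). Dlx4 belongs to the distal-less family of homeobox transcription factors and lies on mouse chromosome 11 beside Dlx3, a regulator of epidermal and hair follicle differentiation. Skin was taken at postnatal day 1 (P1), when the first hair coat is being formed, and at postnatal day 60 (P60), in the adult. The P1 groups held 3 WT and 3 KO samples, and the P60 groups held 2 WT and 2 KO samples. The series asked for molecular changes in skin without Dlx4, so KO was compared with WT at each age, over both ages, and between the ages. The authors listed 36131011 to 74916106 alignments per library, and about 30900000 to 66300000 reads stood behind the RPKM values (reads scaled by gene length and by the alignments of the library). At this depth and replication the median 95% interval of a log2 difference reached 0.284 to either side at P1 and 0.348 at P60 (limma, 14026 tested genes). Changes are given on the log2(RPKM + 0.5) scale, which understates those of genes with low values. All P1 libraries came from 1 sequencing run and all P60 libraries from another, so age and run cannot be told apart.

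Dlx4 itself was lower in KO skin at P1, and at P60 it was under the detection limit in 3 of 4 libraries. The gene spans positions 95140447 to 95146263 on the minus strand of chromosome 11 (mm10), and Dlx3 spans 95120119 to 95125296 on the plus strand. Dlx4 reached 3.38 ± 0.427 RPKM in WT and 1.95 ± 0.443 RPKM in KO skin at P1 (SD, n = 3 each), 42.3% lower in KO. The KO libraries held 1.77, 2.45 and 1.62 RPKM, each below the WT values of 2.93, 3.78 and 3.42. These values rested on about 214 to 295 reads per WT library and 114 to 185 per KO library. A two-sided exact permutation test on RPKM gave p = 0.1, the smallest p that 3 against 3 samples allow. The log2 change was -0.67 (SE 0.16) with an adjusted p of 1 over all genes in limma, while Dlx4 passed when adjusted over the list alone (5 measured Dlx genes). Ranked by p in limma, Dlx4 stood at place 6 among all tested genes at P1 and at place 1 among the 7605 that were lower in KO. The authors' analysis of variance, whose model was not checked here, gave Dlx4 at P1 a ratio of KO over WT of 0.584 with an unadjusted p of 0.616. The values are sums over the whole gene, so they do not show which part of the transcript was read in KO skin. At P60 the WT libraries held 0 and 0.125 RPKM and the KO libraries 0.000294 and 0, where 3 reads correspond to 0.0198 to 0.0307 RPKM. No fold is given for P60, and the genotype of the P60 libraries could not be checked from Dlx4 at this depth.

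The neighbouring Dlx3 had 62.7 ± 5.86 RPKM in WT and 59.1 ± 7.33 RPKM in KO skin at P1 (SD, n = 3 each), a log2 change of -0.09 (SE 0.13) that did not pass in limma and was 0.17 with array weights. The log2 changes at P1 were 0.10 for Dlx1, 0.18 for Dlx2 and 0.29 for Dlx5, with none past the threshold. At P60 the log2 change of Dlx5 was 0.48 (SE 0.17, adjusted p = 0.0865 in limma), that of Dlx1 -0.18, and those of Dlx2 and Dlx3 were 0.11 and 0.07. Both of these turned to -0.1 under quantile normalization, and Dlx3 to -0.07 with median-of-ratios size factors. Dlx6 and the antisense transcripts of the family were under the expression filter and were not tested.

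**Figure D1:**
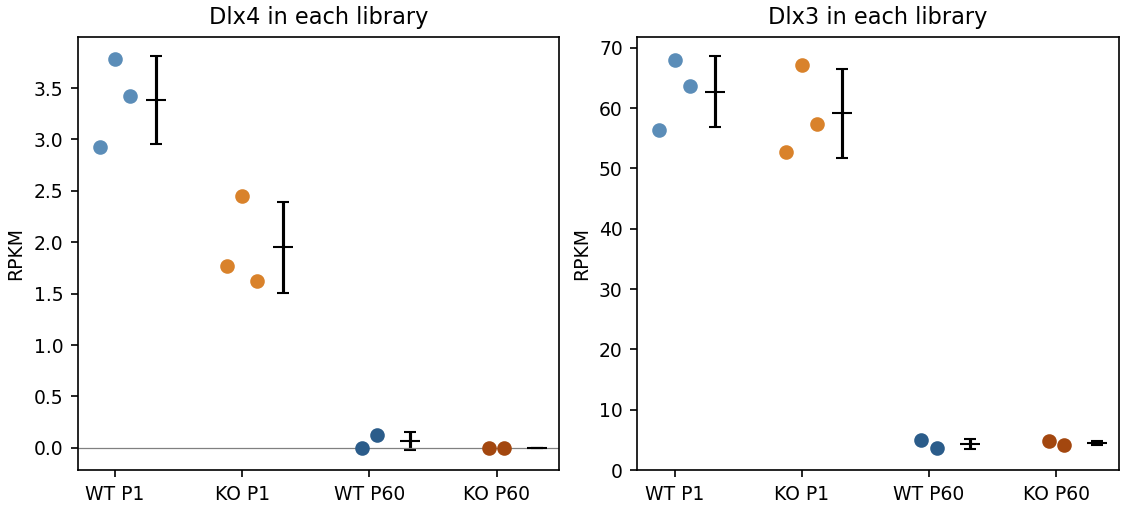
RPKM of Dlx4 (left) and Dlx3 (right) in each library, with 1 point per library and the bar at the group mean ± SD (n = 3 at P1, n = 2 at P60). Dlx4 at P1 lies between 2.93 and 3.78 RPKM in WT and between 1.62 and 2.45 RPKM in KO, whereas the Dlx3 groups overlap at both ages.

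At P1 no single gene separated KO from WT skin after correction, and the differences between gene groups were small. The 20 measured interferon response genes, which viral nucleic acid and interferons induce, were all lower in KO, with a median log2 change of -0.30. Among them Isg15, a ubiquitin-like antiviral modifier, had 6.57 ± 1.17 RPKM in WT and 4.54 ± 0.722 RPKM in KO (SD, n = 3 each), and Usp18, which removes Isg15 from proteins, had 1.78 ± 0.754 and 0.915 ± 0.212 RPKM. The 11 endothelial genes were also all lower (median -0.16), among them the tight junction gene Cldn5 (log2 change -0.44, SE 0.23) and the adherens junction gene Cdh5 (-0.23, SE 0.12). White adipocyte genes were lower in 15 of 16 members (median -0.15), with Pnpla2, which encodes a triglyceride lipase, at -0.52 (SE 0.23). Lists that were higher in KO were cholesterol synthesis (18 of 20 members, median 0.16), melanocytes (12 of 12, 0.17), sebaceous gland (13 of 16, 0.17), inner root sheath (12 of 12, 0.12) and hair keratin-associated proteins (30 of 37, 0.10). The list of outer root sheath, companion layer and stress keratins was higher in 7 of 9 members (median 0.16), with the injury-induced keratin genes Krt6b at 0.67 (SE 0.52) and Krt16 at 0.63 (SE 0.51).

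None of the members of these lists passed over all genes or when adjusted over the list alone, so the calls at P1 rest on the lists as sets. The set test (camera in limma, preset correlation of 0.01) called 10 of the 35 lists at P1, 7 higher and 3 lower, with an adjusted p of 5.55e-12 for the interferon list. With an estimated correlation 0 of the lists were called, and all 10 had an adjusted p = 0.91 with an estimated correlation. The list of sex-linked genes was among those called (median 1.15), and KO P1 replicate 2 alone had 35 RPKM of the Y-linked Eif2s3y, 16 RPKM of the Y-linked Ddx3y and 0.0536 RPKM of Xist, the RNA that silences an X chromosome. The other 5 P1 libraries had 29.2 to 39.8 RPKM of Xist and at most 0.0164 RPKM of Eif2s3y. The interferon genes stood at median log2 differences from the WT mean of -0.274, -0.05 and 0.384 in the WT libraries and -0.221, -0.116 and -0.614 in the KO libraries, so the groups overlapped. An exact permutation test on the mean of the list gave p = 0.3, where 0.1 is the smallest possible. Without WT P1 replicate 3, 8 of the 10 calls ended, with medians of -0.04 for cholesterol synthesis, -0.05 for endothelium, 0.07 for melanocytes, 0.02 for sebaceous gland, 0.01 for inner root sheath and 0 for keratin-associated proteins, while the interferon list (-0.11) and the white adipocyte list (-0.28) were still called. The white adipocyte call ended without WT P1 replicate 2 (-0.02), KO P1 replicate 3 (-0.04) or KO P1 replicate 2 (-0.15). Without KO P1 replicate 2 the calls of melanocytes (0.03), inner root sheath (0.03), keratin-associated proteins (-0.02), stress keratins (0.10) and sex-linked genes (0) ended as well. Without WT P1 replicate 1 the calls of inner root sheath (-0.02), sebaceous gland (0.10), stress keratins (0.14) and sex-linked genes ended, the keratin-associated list was called lower in KO (-0.25), and the medians of cholesterol synthesis and interferon response were 0.27 and -0.46. Without WT P1 replicate 2 the sex-linked call ended, and the medians were 0.26 for cholesterol synthesis, 0.28 for melanocytes, 0.32 for sebaceous gland, 0.38 for inner root sheath, 0.6 for keratin-associated proteins and 0.36 for stress keratins. Without KO P1 replicate 1, where 16 lists in all were called, melanocytes stood at 0.36, inner root sheath at 0.2 and white adipocytes at -0.29, and without KO P1 replicate 3 keratin-associated proteins stood at 0.19. With quantile normalization the keratin-associated, inner root sheath and sex-linked calls ended, and with median-of-ratios factors the keratin-associated call.

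Of single genes at P1, those with the smallest p in each direction are given although they did not pass. Madcam1, an adhesion molecule of mucosal vessels, had 0.486 ± 0.148 RPKM in WT and 2.68 ± 0.798 RPKM in KO (SD, n = 3 each), a log2 change of 1.67 (SE 0.21) with an adjusted p of 0.189 in limma. Mup18, a major urinary protein gene, was at 1.6 (SE 0.31), Hist2h2aa2, a histone gene, at 0.94 (SE 0.20), DQ267102 at 0.78 (SE 0.21) and Top1mt, the mitochondrial topoisomerase, at 0.38 (SE 0.09). After Dlx4, the lower genes were the ribosomal protein pseudogene Rpl31-ps12 at -1.42 (SE 0.36), the potassium channel gene Kcnk3 at -1.02 (SE 0.26), the linker histone gene Hist1h1b at -0.66 (SE 0.17) and the zinc finger gene Zfp433 at -0.55 (SE 0.15). Mup18, Hist2h2aa2 and Rpl31-ps12 have near-identical copies elsewhere in the genome, so the share of reads given to each is uncertain. In limma 0 of 14026 genes passed at P1, and 130 had an unadjusted p under 0.05 where chance gives 701. The authors' own table listed 290 of 21208 genes at p under 0.05 and 2 at q under 0.05, none of the latter among the genes tested here. The libraries of the genotypes did not overlap for 640 genes, or 4.6% where chance gives 10%. Array weights gave 26 genes and no expression filter gave 2.

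In adult skin at P60, genes of the dermal matrix and of immune cells were higher in KO, and genes of skeletal muscle were lower. Col1a1, the main collagen of dermis, rose from 1710 ± 213 RPKM in WT to 6220 ± 3630 RPKM in KO (SD, n = 2 each; log2 change 1.73, SE 0.35, adjusted p = 0.0308 in limma), and Col3a1 from 942 ± 205 to 3350 ± 1910 RPKM (1.72, SE 0.33). Col1a1 lies on chromosome 11 like Dlx4 (positions 94936224 to 94953042) and is in the list of Dlx4 chromosomal neighbours. That list was not called at P60. It stood at median log2 differences from the WT mean of -0.02 and 0.02 in WT and -0.028 and 0.074 in KO. All 20 measured genes of the list of dermal fibroblasts and matrix were higher (median 1.22), and 16 of them rose over all genes and 19 when adjusted over the list alone, among them Col5a2 (1.58, SE 0.31), Col6a2 (1.27, SE 0.25) and Col6a1 (1.23, SE 0.23). Macrophage, dendritic and Langerhans cell genes were higher in 14 of 14 members (median 1.15), of which 10 rose and 12 when adjusted over the list alone. They included the macrophage surface gene Adgre1 (3.44 ± 1.45 to 10.6 ± 2.11 RPKM, SD, n = 2 each), the scavenger receptor gene Cd163 (log2 change 1.47, SE 0.30), the mannose receptor gene Mrc1 (1.31, SE 0.23) and H2-Aa, an antigen-presenting MHC class II chain (1.14, SE 0.24).

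The 8 mast cell genes were all higher at P60 (median 0.84), and 2 rose, the protease genes Cpa3 (1.66, SE 0.33) and Cma1 (0.96, SE 0.26), with 5 when adjusted over the list alone. Mcpt4, another mast cell protease gene, was at 1.21 with an adjusted p of 0.0501 in limma. All 7 T cell genes were higher (median 0.65), and 3 rose, with 4 when adjusted over the list alone. These were the adhesion receptor gene Cd2 (0.77, SE 0.19), the T cell receptor subunit gene Cd3g (0.70, SE 0.19) and the kinase gene Lck (0.65, SE 0.17). In the list of barrier lipid metabolism, which builds the lipid layers of the cornified epidermis, 18 of 19 genes were higher (median 0.29) and 4 rose, also 4 when adjusted over the list alone. They were Lipn, a lipase gene (0.68, SE 0.17), Sdr9c7, a dehydrogenase gene (0.60, SE 0.11), Abca12, the lipid transporter of lamellar granules (0.58, SE 0.12), and Ugcg, the glucosylceramide synthase (0.45, SE 0.10).

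All 20 skeletal muscle genes were lower in KO at P60 (median -0.93), although 1 of them, the fast myosin gene Myh1, fell in the test (1440 ± 399 to 769 ± 171 RPKM, SD, n = 2 each; log2 change -0.89, SE 0.22), also 1 when adjusted over the list alone. Casq1, the calcium store protein of muscle, was at -0.96 with an adjusted p of 0.056 in limma, and the calcium channel gene Ryr1 was at -0.91 with 0.0594. The muscle genes held 14.9% and 16.5% of the summed RPKM in the WT libraries at P60 and 6.94% and 11.3% in the KO libraries, against 1.56% to 3.05% at P1. The matrix list stood at median log2 differences from the WT mean of -0.287 and 0.287 in WT and 1.599 and 0.899 in KO, so KO P60 replicate 1 had both the lowest muscle share and the highest matrix values. Genes of the endothelium (median 0.18) and of basal epidermis (0.21) moved less, and neither list was called. The set test (camera, preset correlation) called these 6 lists of 35, with adjusted p from 1.1e-08 for muscle and 1.14e-08 for matrix to 0.04 for T cells. All 6 had an adjusted p = 0.946 with an estimated correlation, where 0 lists were called. The rotation test fry called 3, the matrix, macrophage and barrier lipid lists. Without KO P60 replicate 1 the mast cell, T cell and barrier lipid calls ended (adjusted p of 0.105, 0.213 and 0.058), without WT P60 replicate 2 the T cell and barrier lipid calls ended (0.0803 and 0.185), without WT P60 replicate 1 the mast cell call ended (0.111), and the T cell call also ended without KO P1 replicate 1. The matrix median was 0.90 and the muscle median -0.48 without KO P60 replicate 1, and the muscle median was -0.56 with quantile normalization. The barrier lipid median was 0.46 without WT P60 replicate 1 and 0.18 without WT P60 replicate 2.

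**Figure D2:**
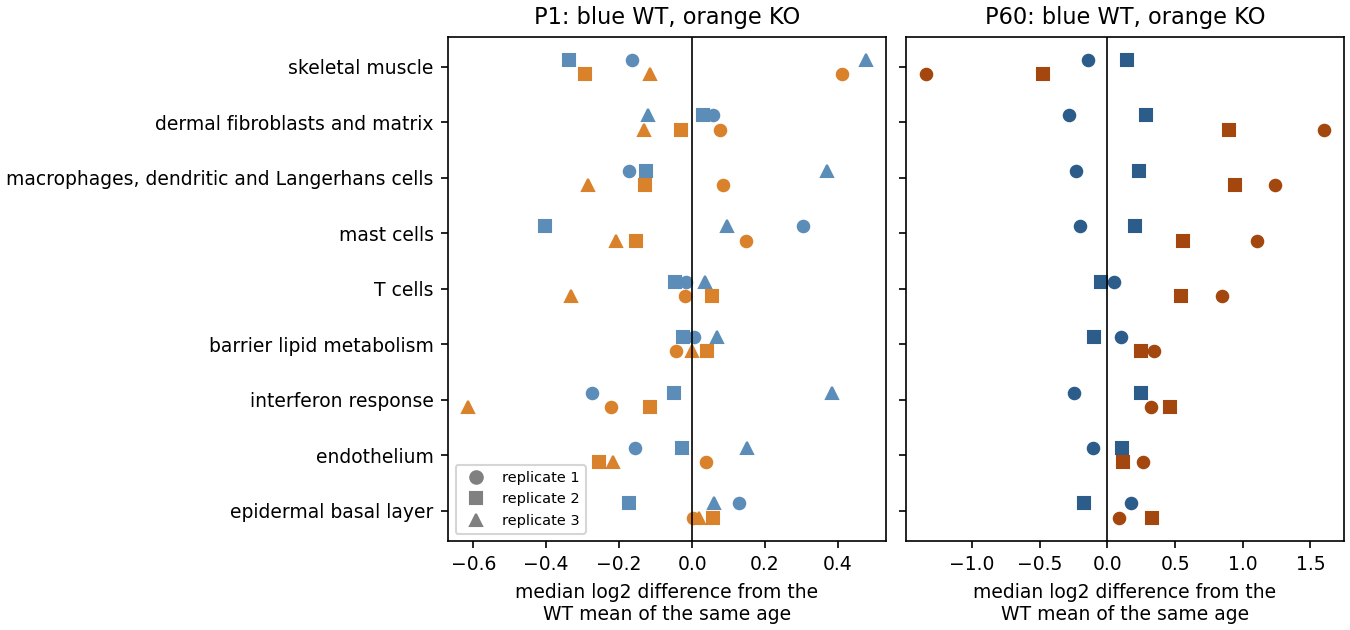
Median log2 difference of each gene list from the WT mean of the same age, with 1 point per library, WT in blue, KO in orange and the replicate number as the shape (P1 left, P60 right). At P60 the matrix list lies at 1.599 and 0.899 in the KO libraries and the muscle list at -1.339 and -0.477, while at P1 the genotypes overlap.

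Among the single genes named at P60, the largest rise was that of Sprr4, a small proline-rich protein gene of the cornified envelope, from 2.61 ± 2.42 to 19.4 ± 11.6 RPKM (SD, n = 2 each; log2 change 2.81, SE 0.56, adjusted p = 0.0308 in limma). Cpz, which encodes an extracellular carboxypeptidase, rose by 1.69 (SE 0.33). Cd300ld3 (2.03), the eosinophil-type ribonuclease genes Rnase2b (1.82) and Ear2 (1.73) and the signal recognition particle gene Srp54b (1.75) also passed, but each has near-identical copies, so its share of reads is uncertain. The largest fall was that of Chac1, a glutathione-degrading enzyme induced by amino acid stress, from 31.7 ± 4.31 to 8.81 ± 0.717 RPKM (SD, n = 2 each; log2 change -1.79, SE 0.27). Further genes that fell were Snai3, a Snail-type repressor (-1.57, SE 0.29), Padi2, a peptidylarginine deiminase (-1.46, SE 0.26), Abra, which encodes an actin-binding protein of muscle (-1.33, SE 0.22), and Nr4a1, an immediate early nuclear receptor (-1.27, SE 0.25). Ctxn3 (-1.24, SE 0.31), the potassium channel gene Kcnc4 (-1.20, SE 0.32) and Serpinb1c (-1.31, SE 0.26), a serpin with close copies, fell as well. The authors' analysis of variance, whose model was not checked here, gave Sprr4 an unadjusted p of 0.12 and Chac1 one of 0.151. Among the falls named here its unadjusted p was lowest for Padi2 (0.0371), followed by Kcnc4 (0.0802), and highest for Ctxn3 (0.29). Among the rises named here it ran from 0.00584 for Cpz to 0.12 for Sprr4.

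**Figure D3:**
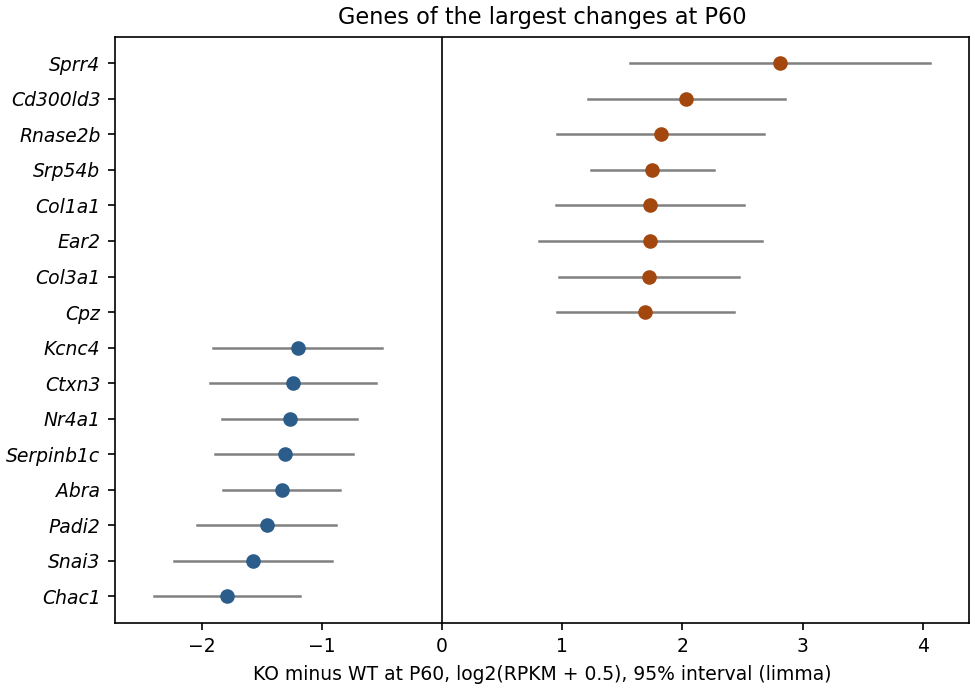
KO minus WT at P60 on the log2(RPKM + 0.5) scale for the 8 named genes of the largest changes in each direction, with the 95% interval from limma as the line. Changes run from 2.81 for Sprr4 down to -1.79 for Chac1.

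In total limma called 1560 of 14026 genes at P60, 1152 higher and 408 lower in KO, and 4496 had an unadjusted p under 0.05 where chance gives 701. The libraries of the genotypes did not overlap for 8624 genes, or 61.5% where chance gives 33.3%. The authors' table gave p-values for 21208 genes at P60, a larger set than the genes tested here. It held 9 genes at q under 0.05, 0 of them among the genes tested here. At p under 0.05 it held 1513 of the 21208, which included 580 of the 1560 genes. The model behind the authors' p-values was not checked here, so this overlap need not be one of like tests. The direction of the total depended on scaling, since the median of all genes was 0.127 at P60 as deposited and 0 with median-of-ratios size factors. As deposited 73.8% of the called genes were higher, against 33.1% of 1482 with those factors and 34.5% of 55 with quantile normalization, and relative to the shifted median the matrix list stood at 1.07 and the muscle list at -1.08. The count also changed with single libraries, of which those of P1 enter through the shared estimate of spread alone. It was 0 without KO P60 replicate 1, 0 without KO P1 replicate 2, 1 without WT P60 replicate 1, 3 without WT P1 replicate 1, 29 without KO P1 replicate 3, 630 without KO P1 replicate 1, 763 without WT P60 replicate 2 and 2435 without WT P1 replicate 3, and it was 2 with the replicate block, 0 with the P60 libraries alone and 0 with the share of muscle transcripts as a covariate, an alternative chosen after seeing the data.

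Averaged over P1 and P60, a single gene differed between the genotypes. Spred2, an inhibitor of Ras and MAP kinase signalling, had 11 ± 0.347 RPKM in WT and 12.5 ± 0.545 RPKM in KO at P1 (SD, n = 3 each) and 2.5 ± 0.0477 and 5.61 ± 0.236 RPKM at P60 (SD, n = 2 each). Its KO libraries, at 11.9 to 13 and 5.44 to 5.78 RPKM, lay above the WT libraries, at 10.6 to 11.3 and 2.47 to 2.54 RPKM. Its mean log2 change was 0.60 (SE 0.06, adjusted p = 0.0344 in limma). With the replicate block 1 gene passed, which was not Spred2. The next genes did not pass (adjusted p = 0.157 in limma), with mean log2 changes of 0.56 for Clca3a2, 0.56 for Tspan18, 0.54 for the actin regulator Wasf2 and 0.51 for Fam8a1, and of -0.62 for Pgpep1l, -0.45 for Asb5, -0.37 for the kinase gene Mapk12, -0.37 for Hspa1l and -0.32 for Ecsit. The set test called 6 lists, of which the matrix (20 of 20 higher, median 0.59), macrophage (14 of 14, 0.44), barrier lipid (18 of 19, 0.22), and muscle (20 of 20 lower, -0.46) lists had also been called at P60. All 6 lists had an adjusted p = 0.938 with an estimated correlation, where 0 were called. The matrix, macrophage and muscle averages came from P60, with mean log2 changes of 1.23 (SE 0.28), 1.07 (SE 0.24) and -0.87 (SE 0.42). At P1 these were -0.04 (SE 0.22), -0.14 (SE 0.19) and 0.03 (SE 0.34). Sebaceous gland genes were higher in 16 of 16 members (0.45), with Elovl3, a fatty acid elongase gene, at 0.56 (SE 0.21), and Wnt/beta-catenin targets in 12 of 13 (0.20), with the Wnt inhibitor genes Apcdd1 at 0.57 (SE 0.09) and Nkd2 at 0.30 (SE 0.09). The sebaceous list stood at median log2 differences from the WT mean at P60 of 0.399 and -0.399 in WT and 1.192 and 0.256 in KO. Its call and that of the Wnt targets ended without KO P60 replicate 1 (medians of 0.18 and 0.19), without WT P60 replicate 2 (0.26 and 0.13), where the barrier lipid call ended as well (0.14), and without WT P1 replicate 3 (0.41 and 0.24). The Wnt call also ended without WT P1 replicate 2 and without KO P1 replicate 1, and its median was 0.32 without WT P60 replicate 1. The muscle median was -0.24 without KO P60 replicate 1, -0.30 without WT P1 replicate 3 and -0.28 with quantile normalization. No member passed over all genes, while 19 matrix, 6 macrophage, 3 barrier lipid and 1 Wnt target genes did when adjusted over the list alone, and 0 sebaceous or muscle genes. Of all genes 2820 had an unadjusted p under 0.05, and the count of 1 became 584 without KO P60 replicate 2, 92 without WT P60 replicate 2 and 0 without each of the other 8 libraries. It was also 0 with median-of-ratios factors and with quantile normalization, and 12 lists were called without WT P1 replicate 1.

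The difference of the KO effect between the ages was tested directly, as P60 minus P1. Sex and the sequencing run moved with age, so this difference cannot be told apart from a KO effect that differs by sex or run. Matrix genes (20 of 20 positive, median 1.25) and macrophage genes (14 of 14, 1.33) differed most, with Col5a2 at 1.67 (SE 0.40), the small proteoglycan genes Lum at 1.6 (SE 0.40) and Dcn at 1.52 (SE 0.37), and Adgre1 at 1.64 (SE 0.31). Mast cell (8 of 8, 0.94), interferon response (20 of 20, 0.74), T cell (7 of 7, 0.69) and barrier lipid genes (18 of 19, 0.29) were positive as well, and muscle genes (20 of 20 negative, -0.91) were negative. Within the interferon list Usp18 stood at 1.36 (SE 0.44). Hair keratin-associated protein genes had a median of -0.12 with 9 of 37 positive. These genes were near 0 RPKM at P60 (library means of -0.82 to -0.74 on the log2 scale). A KO effect could hardly be seen there, so the value mostly restates their P1 change with its sign turned. This median turned to 0.22 without WT P1 replicate 1, 0.01 without WT P1 replicate 3 and 0.03 without KO P1 replicate 2. It was -0.62 without WT P1 replicate 2 and -0.22 without KO P1 replicate 3. Camera called these 8 lists of 35, and all 8 had an adjusted p = 0.943 with an estimated correlation. The mast cell call ended without KO P60 replicate 1, WT P60 replicate 1 or WT P1 replicate 3 (0.66, 0.72 and 0.84), the T cell call without KO P60 replicate 1 or WT P60 replicate 2 (0.53 and 0.52), the barrier lipid call without KO P60 replicate 1, WT P60 replicate 2, WT P1 replicate 1 or WT P1 replicate 3 (0.24, 0.20, 0.29 and 0.28), and the keratin-associated call also without either of WT P60 replicate 2 and KO P60 replicate 2 (-0.14 and -0.16). The muscle median was -0.48 without KO P60 replicate 1. With quantile normalization the keratin-associated call ended (-0.21), and with median-of-ratios factors the barrier lipid and keratin-associated calls ended (medians of 0.12 and -0.14). No member passed over all genes. When adjusted over the list alone, 17 matrix, 12 macrophage, 4 barrier lipid, 4 T cell, 3 mast cell and 3 interferon genes did, and 0 muscle or keratin-associated genes.

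No single gene passed the test of the difference in limma (0 of 14026, smallest adjusted p = 0.0878), and 3214 had an unadjusted p under 0.05. The genes of the smallest p were Fam8a1 (1.22, SE 0.14), Sla, an adaptor gene of lymphocytes (1.25, SE 0.18), Wasf2 (1.08, SE 0.16), Pygl, a glycogen phosphorylase gene (0.86, SE 0.13), and Spred2 (0.85, SE 0.12) on the positive side. On the negative side were Abra (-1.75, SE 0.28), the muscle thin filament gene Lmod2 (-1.35, SE 0.17), the glycogen-targeting subunit gene Ppp1r3c (-1.17, SE 0.16), the imprinted gene Snrpn (-0.96, SE 0.16) and Ecsit (-0.81, SE 0.13). Of the 1560 genes called at P60, 650 (41.7%) had the same sign at P1, and the log2 changes at the ages had r = -0.08 across genes, which are not independent replicates. The count of 0 became 784 without KO P60 replicate 2, 267 without WT P60 replicate 2, 1 without WT P1 replicate 2, 465 with array weights, 19 with no filter, 3 with median-of-ratios factors and 2 with a pseudocount of 0.1.

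Adult skin had lower levels of hair-forming and cell division transcripts than newborn skin and higher levels of muscle transcripts. Inner root sheath genes, which build the inner sleeve of the growing hair, fell in 12 of 12 members (median log2 change -7.32), hair shaft keratins in 15 of 15 (-5.60) and hair keratin-associated proteins in 37 of 37 (-5). In WT skin Krt71 went from a mean of 772 RPKM at P1 to 0.119 RPKM at P60, the trichohyalin gene Tchh from 379 to 0.655, and the hair cortex keratin gene Krt35 from 95.2 to 0.192. Cell cycle genes fell in 25 of 25 members (-3.26), among them the mitotic kinase genes Aurkb (-3.64, SE 0.10) and Plk1 (-3.47, SE 0.13). Melanocyte genes fell in 12 of 12 (-3.38), with the pigment genes Dct at -5.66 and Pmel at -5.13, and mast cell genes in 8 of 8 (-2.67). Of the hair follicle differentiation regulators 16 fell and 2 rose (median -2.59), with the signalling gene Shh at -4.80 and Dlx3 at -3.64 (SE 0.10). Wnt/beta-catenin targets fell in 13 of 13 (-2) with Lef1 at -3.80, and 11 of 13 dermal papilla genes fell (-1.89) with the proteoglycan gene Vcan at -3.88. In the imprinted growth network 11 genes fell and 1 rose (-2.53), with the growth factor gene Igf2 at -6.30 (SE 0.16). Within the Dlx family Dlx4 fell by 2.53, Dlx2 by 2.67 and Dlx1 by 2.28, whereas Dlx5 rose by 0.52 (SE 0.11).

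Skeletal muscle genes rose in 18 of 20 members with age (median 3.13), including the adult fast myosin genes Myh4 (8.84, SE 0.33) and Myh1 (5.66, SE 0.14), while the 2 that fell were the developmental myosin genes Myh8 (-7.99, SE 0.16) and Myh3 (-4.88, SE 0.16). Circadian clock genes rose in 11 of 15 members and fell in 4 (median 1.67), with the output regulator Dbp at 5.15 (SE 0.09) and the clock repressor Nr1d1 at 3.76 (SE 0.16). Macrophage, dendritic and Langerhans cell genes rose in 10 of 14 and fell in 1 (0.88), with the MHC class II genes H2-Eb1 at 4.86 and H2-Aa at 4.48. T cell genes rose in 4 of 7 and fell in 2 (1.06), with Cd3e at 2.58, and Schwann cell and nerve genes rose in 7 of 10 and fell in 3 (1.14), with Mbp, a myelin gene, at 2.17. The macrophage median was 1.27 with median-of-ratios factors and 1.36 with quantile normalization, where that of T cells was 1.61. The T cell call ended with median-of-ratios factors (median 1.34) and without KO P60 replicate 1 (0.97). The Schwann cell call ended with median-of-ratios factors (1.55), with quantile normalization (1.37), without WT P1 replicate 3 (1.2) and without WT P60 replicate 1 (1.14). The counts in these lists were the same when adjusted over the list alone. The largest rises among named genes were Retnla, a resistin-like gene of macrophages and adipose tissue (8.92, SE 0.25), Myh4, the calcium buffer gene Pvalb (8.24, SE 0.37), Mb, the oxygen store of muscle (6.30, SE 0.25), Inmt (6.14, SE 0.40), Fcgbp (6.12, SE 0.09) and the cytochrome gene Cyp2e1 (5.97, SE 0.59). Mup10 (6.53), Rpl31-ps12 (6.77) and Rplp2-ps1 (6.68) also rose but share reads with close copies. The largest falls among them were the inner root sheath genes Krt25 (-10.37, SE 0.17), Krt71 (-10.32, SE 0.17), Krt27 (-9.24), Krt73 (-8.22), Tchh (-8.18) and Krt28 (-7.94), with Myh8, and BC100530 (-9.37), Stfa3 (-9.02) and Hist1h2ao (-8.30), which have close copies. Where a gene was near 0 RPKM at one age, its log2 value is set by the pseudocount of 0.5 and is not a measured fold.

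**Figure D4:**
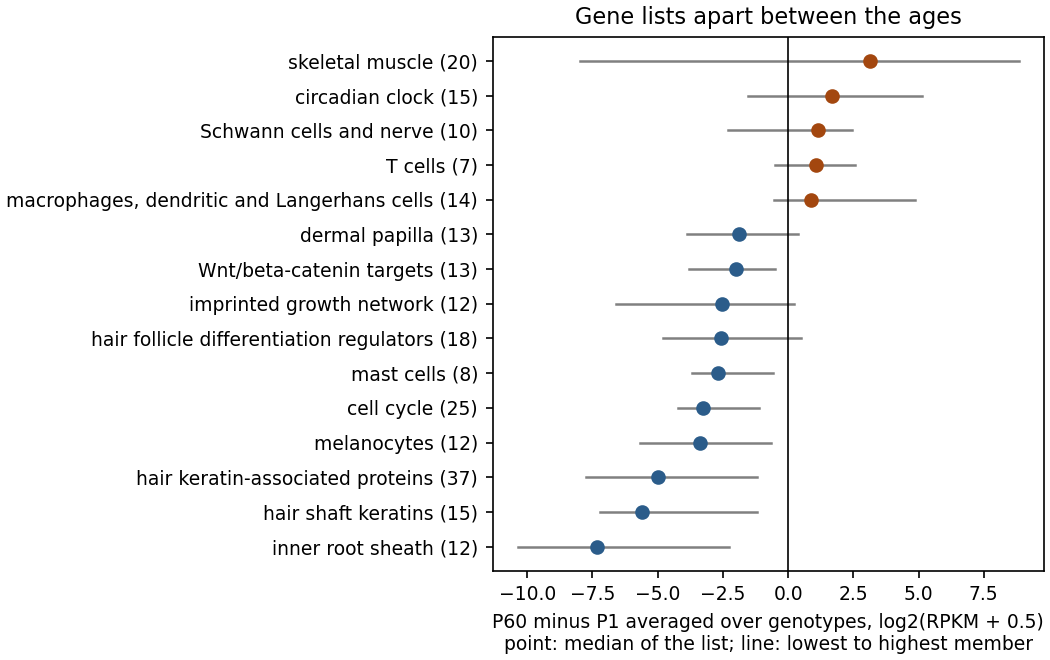
Median log2 change from P1 to P60, averaged over genotypes, of each list that camera called, with the lowest and highest member as the line and the number of measured genes in brackets. Medians run from 3.13 for skeletal muscle to -7.32 for the inner root sheath.

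In limma 11456 genes differed between the ages, 3415 higher and 8041 lower at P60, and camera called 15 lists, 5 higher and 10 lower. The lists called for age had adjusted p = 0.582 to 0.626 with an estimated correlation, where 0 were called, and fry called 30. The median of all genes was -0.389 as deposited and 0.004 with median-of-ratios factors, and the share of called genes that were higher was 29.8% as deposited, 50% with those factors and 48.2% with quantile normalization. All P60 libraries carried Y-linked transcripts, with Eif2s3y at 22.3 to 26.9 RPKM and Xist at 0.0477 to 0.105 RPKM, whereas 5 of the 6 P1 libraries carried Xist, so sex moved with age as well as with the sequencing run. Libraries of the same group had correlations of log2 values of 0.972 to 0.993, those of the other genotype at the same age 0.964 to 0.994, and those of the other age 0.745 to 0.836.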

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

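The tests on muscle share, on single libraries and on immune cells were chosen after the results had been seen, and the tests on gene length and GC and on other splits of the samples before. The requirement that a value pass its bound by more than its spread was also set after the values had been seen.

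A difference between the ages in the KO effect, tested directly with camera, singled out 8 gene lists. The median difference, P60 minus P1, was 1.33 for macrophages, dendritic and Langerhans cells, 1.25 for dermal fibroblasts and matrix, 0.94 for mast cells, 0.74 for the interferon response, 0.69 for T cells and 0.29 for barrier lipid metabolism. It was -0.91 for skeletal muscle and -0.12 for hair keratin-associated proteins. The keratin-associated genes were near 0 RPKM at P60, so their value mostly restates the P1 change with its sign turned and shows no separate effect at P60. None of the 8 was called with an estimated correlation. Since sex and the sequencing run moved with age, these differences cannot be told apart from a KO effect that differs by sex or run.

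At P60 the matrix list was higher and the muscle list lower in KO skin. A smaller share of muscle RNA, which raises all other cell types alike, was argued against by the mean log2 change of the matrix list, which exceeded that of the endothelium and basal epidermis lists by 1.04 (SE 0.30). KO P60 replicate 1 alone was argued against as the whole cause of the higher matrix list, since its median was 0.90 without that library. Medians ran from 0.90 to 1.6 over the P60 libraries left out, and camera at the preset correlation still called the list. A single KO library then remains, so the spread between KO samples is not measured, and the calls of single genes did not hold without KO P60 replicate 1. With all libraries and an estimated correlation the matrix list was not called (adjusted p = 0.946). A trend with gene length or GC was argued against, since the median was 1.07 after it was removed. An effect of the genotype, a different depth of dissection that took more dermis and less muscle, and other differences between the 4 samples may each account for the pattern and stay open and untested, since the labels give no depth of dissection.

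At P1 all 20 interferon response genes were lower in KO skin. Without either WT P1 replicate 3 or KO P1 replicate 3 the highest median was -0.11 (camera adjusted p = 0.00446). Over the P1 libraries left out, medians ran from -0.46 to -0.11 and camera adjusted p from 3.26e-17 to 0.00446. The list mean with all libraries had a standard error of 0.22 between libraries. A share of WT P1 replicate 3 or KO P1 replicate 3 in the pattern thus cannot be told apart from an effect of the genotype. With all libraries and an estimated correlation the list was not called (adjusted p = 0.91). Fewer immune cells in KO skin could not be excluded either, since the T cell median at P1 was -0.16 with 3 of 7 genes higher and the macrophage median -0.10 with 2 of 14 higher, where a fall of 0.15 in both lists had been set for it and medians above -0.10 in both against it. Both explanations stay open, as does a biological one, because the exact permutation p of the list mean was 0.3.

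Other splits of the samples were counted to ask whether chance can be excluded. At P1 the real split gave 0 genes and the highest other split 1, with 10 of 10 splits giving as many as the real one, and at P60 the real split gave 1560 genes and the highest other 0, with 1 of 3, and in both cases the splits are too few for a share under 0.05. For the average over ages the real split gave 1 gene and the highest other 561, with 13 of 60 splits giving as many, so chance cannot be excluded. For the difference between ages the real split gave 0 genes and the highest other 561, and all 60 of 60 splits give as many as 0, so this count decides nothing, as with the count at P1. The split with 561 genes set WT P1 replicates 1 and 2 and KO P1 replicate 3 against WT P1 replicate 3 and KO P1 replicates 1 and 2, and it parted the P60 libraries by genotype. For the average, the P60 libraries were parted as in the real split, so the rise from 1 to 561 genes came from regrouping the P1 libraries. That regrouping acts through the P1 part of the contrast and through the shared estimate of spread. The same grouping of the P1 libraries gave 0 genes at P1 alone, and these 2 routes were not tested apart. For age the real split gave 11456 genes and the highest other 7, with 1 of 100 splits giving as many, the smallest share that 100 splits allow. This argues against chance, while the sequencing run and sex stay confounded with age.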

How the results depend on the processing

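The muscle share as a covariate, scaling without the muscle genes, the pseudocount of 0.1 without moderation and camera with a variance trend were chosen after seeing the data. Dlx4 at P1 was lower in KO under all 22 alternatives (-0.81 to -0.33) and passed in 0 of them, and the filter on a mean of 5 RPKM removed it and gave no value. The number of genes at P1 was 0 in every setting but 2, and the age count lay between 7416 and 13657 in the settings that gave one, which the muscle share as a covariate and the libraries of an age alone did not. The count at P60 lay between 0 and 3216. Where no reason is given the cause was not tested. Genes with few reads limit the log2 values, which depend on the pseudocount there.

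Camera with an estimated correlation called 0 lists at P1, 0 at P60, 0 for the average, 0 for the difference and 0 for age, and fry, which asks another question, called 0, 3, 0, 0 and 30. Camera with a variance trend called 13 lists at P1 and 5 at P60. With a pseudocount of 0.1 the average gave 2 genes and the difference 2, and with 1 the average gave 0. With no filter, which adds genes with low values to the correction, P1 gave 2 genes and 4 lists, P60 502 genes, the average 9 and the difference 19. With a mean of at least 5 RPKM, which tests fewer genes, age gave 7416 genes and the difference 4 lists. With median-of-ratios factors the average gave 0 genes, the difference 3, and Dlx3 at P60 was -0.07. With quantile normalization P60 gave 55 genes, the average 0 genes and 11 lists, age 23 lists, and Dlx2 and Dlx3 at P60 were -0.1 and -0.1. The P60 libraries alone, with few degrees of freedom, gave 0 genes. Array weights gave 26 genes at P1, 741 at P60, 3 for the average and 465 for the difference, and turned Cxcl10 to 0.01, Krt16 to -0.23 and Dlx3 to 0.17 at P1. An adjusted p under 0.1 gave 3216 genes at P60 and 3 for the difference. With the muscle share as a covariate P60 gave 0 genes and 12 lists, the average 0 genes, Dlx3 at P60 was -0.1 and the muscle list 0.02, which the covariate itself removes. Scaling without the muscle genes gave 0 genes for the average, and a pseudocount of 0.1 without moderation gave 198 genes at P60.

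With the replicate number as a block P60 gave 2 genes, the average gave 1 gene that was not Spred2, and the samples share only a number, so the block is not a known pairing.

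Leaving out each library in turn, the count at P60 ranged from 0 (without KO P1 replicate 2, and without KO P60 replicate 1) to 2435 (without WT P1 replicate 3), that for the average from 0 to 584 (without KO P60 replicate 2) and that for the difference from 0 to 784 (without KO P60 replicate 2). Lists called ranged from 5 (without WT P1 replicate 3) to 16 (without KO P1 replicate 1) at P1, from 3 (without KO P60 replicate 1) to 9 at P60, from 4 to 12 (without WT P1 replicate 1) for the average and from 5 (without KO P60 replicate 1) to 11 for the difference. At P1 Nsdhl ranged from -0.03 to 0.37, Fdps from -0.06 to 0.31 and the cholesterol list from -0.04 to 0.27, each lowest without WT P1 replicate 3, as was Krt16 (-0.1 to 1.06). Krtap4-13 ranged from -0.06 to 0.62, Krtap5-1 from -0.02 to 0.4, Krt71 from -0.02 to 0.46, Krt25 from -0.02 to 0.45, the list of hair keratin-associated proteins from -0.25 to 0.6 and the inner root sheath list from -0.02 to 0.38, each lowest without WT P1 replicate 1 and highest without WT P1 replicate 2. Eif2s3y ranged from -0.02 (without KO P1 replicate 2) to 3.06. At P60 Dlx2 ranged from -0.13 to 0.36 and Dlx3 from -0.12 to 0.26, lowest without WT P60 replicate 2. The keratin-associated list for the difference ranged from -0.62 to 0.22 (without WT P1 replicate 1). Of the 6 lists called at P60, 120 of 143 alternative values kept their direction and call, 22 lost the call and 1 turned, and of the 10 at P1 180 of 239 kept them, 55 lost the call and 4 turned.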

Other observations

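The gene families and the tests in this part were chosen after the P60 values had been seen, except that the bounds of the covariate test were set before its value was seen. Genes of the mitochondrial respiratory chain, which pass electrons to oxygen and make ATP, were lower in KO skin at P60. Of 90 measured genes of the chain 84 were lower and 28 fell in limma (median log2 change -0.50), and at P1 the median was 0. Of 46 genes named Nduf, which encode complex I and its assembly factors, 44 were lower and 18 fell (median -0.53), among them Ndufs3 (-0.76, SE 0.13), Ndufa9 (-0.63, SE 0.13) and Ndufv2 (-0.61, SE 0.12). The 17 Atp5 genes of ATP synthase had a median of -0.51 with 6 fallen, and the 78 mitochondrial ribosomal protein genes Mrpl and Mrps a median of -0.30 with 12 fallen. The medians of the respiratory chain, Nduf, Atp5, and Mrpl and Mrps were -0.65, -0.68, -0.66 and -0.44 with median-of-ratios size factors, -0.38, -0.45, -0.33 and -0.34 with quantile normalization, and -0.29, -0.35, -0.29 and -0.21 without KO P60 replicate 1. Cytosolic ribosomal protein genes (92 genes named Rpl and Rps) had a median of -0.04, which was -0.2 with median-of-ratios factors, 0.03 with quantile normalization and 0.03 without KO P60 replicate 1.

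Outside the matrix list, 25 genes whose names begin with Col had a median of 0.19 at P60 with 22 higher and 7 risen, which was 0.09 with median-of-ratios factors, 0.31 without KO P60 replicate 1 and 0.43 with the muscle share as a covariate, and turned to -0.02 with quantile normalization. The 27 H2- genes of the major histocompatibility complex, 3 of them also in the macrophage list, had a median of 0.56 with 6 risen and 25 higher, against -0.19 with 24 lower and none changed at P1. All 22 measured chemokine genes named Ccl and Cxcl were higher at P60 (median 0.53, and 0.36 without KO P60 replicate 1), although 0 passed in limma.

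Since muscle is rich in mitochondria, a hypothesis is that less muscle RNA in the KO samples may account for the lower respiratory chain genes at P60. With the muscle share as a covariate the median of the 90 genes was -0.33 (the standard error of their mean between libraries was 0.14), against -0.50 without it. The value lay below the bound of -0.20 that had been set against the hypothesis, but by less than its spread, so the hypothesis and an effect of the genotype cannot be told apart from these 4 libraries.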
